A study of Arabidopsis thaliana with 8 samples.

How the data were processed

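The series lists 7 RNA-seq libraries and 1 bisulfite sequencing library, and the bisulfite library was the one analysed here. It was made from leaf DNA of 1 plant grown with 16 hours of light and 8 hours of dark. Per the labels' protocols, 500 ng of DNA was sheared, converted with a bisulfite kit and amplified for 14 cycles. The submitters' processing notes name BSMAP 2.89, TopHat2 2.0.9, deepTools and the genome build TAIR10, without saying which tool made which file. Adapter, quality and duplicate filters are not given in the sources used here.

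The authors deposited a table with a row for each cytosine, 42932187 rows in all. Per the file headers, it gives the count of C reads and the count of C or T reads, and for the opposite strand the count of G reads and of G or A reads. The deposited table also holds an effective C+T count, an estimated count that need not be whole. It differed from the plain count in 1117248 rows, and in each of these it equalled the plain count times the G share of the opposite strand within 0.011 reads. The deposited methylation level is a fraction, the C count over the effective count within 0.002 in all but 3 rows, and it was NA in 566 rows. No site had more than 101 reads. Chloroplast sites had a median of 101, so depth was cut off there by a ceiling. Rows whose neighbouring bases gave no readable context numbered 112 and were left out.

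Levels were computed as summed C reads over summed C and T reads at sites with at least 4 reads, and are given in percent. Exact intervals are Clopper-Pearson 95% intervals. Amplified reads without molecular identifiers are not independent molecules, so these intervals cover counting error only. Region differences have 95% intervals from 1000 bootstrap draws of 100-kb windows, and were called where the interval excluded 0. The centromere position of each chromosome was the middle of the longest interval between listed cytosines. It lay 0.323 to 1.05 Mb from the middle of the 2 Mb with the fewest protein-coding genes, on either side.

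Genes came from a table of RefSeq genes on the assembly TAIR10.1, whose name differs from the build of the file. To test whether both use the same positions, the bases given with each cytosine were joined into sequence. The conserved B box of tRNA genes lay at its canonical distance from the annotated 3' end in 571 of 625 nuclear tRNA genes. After moving the annotation by 1 to 1000 bp in either direction it did so in at most 2. Printed positions are those of cytosines in the file. The table gives no strand and no exons. The plan named 1 kb upstream, coding exons, introns, untranslated regions and transposon genes. In their place, 1 kb on both sides of each gene, whole gene bodies and the table's own classes were used. The flanks of a named gene can hold parts of its neighbours, while the flank class of all genes leaves out every annotated gene.

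Protein-coding genes with at least 20 cytosines of each context entered the class test, 26052 genes, and 1380 did not. Each context was tested with a one-sided exact binomial test against the mean of all protein-coding genes, 15.6% in CG, 1.58% in CHG and 0.811% in CHH. Genes past an adjusted p of 0.05 in CG alone were called gene body methylated, and genes past it in CHG or CHH transposon-like. Reads in a gene are not independent, so these classes describe this library. Gene groups were compared with two-sided Fisher's exact tests. Random genes of the same length were drawn 10000 times within 20 length bins.

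The gene lists and the rule for named genes were fixed before the data were examined. The rule takes all genes of 7 lists (86 genes) whose ID and name are in the gene table, which held for 78 in 6 lists, since none of the 4 listed transposon genes was in it by name. Per list it names the count above 10% in each context and up to 4 genes with the highest and 2 with the lowest levels. It adds the 10 genes with the highest CHG level and the 10 gene body methylated genes with the highest CG level, among genes with at least 50 cytosines of that context and 0.5 to 2 times the median depth. MORC6 is listed in the table as DMS11, with MORC6 as a synonym. Listed genes were tested against the chloroplast rate.

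The gene test was tested on simulated data over 26052 genes with the real read numbers. All of 100 genes raised 1.5-fold in CG and all of 100 raised 3-fold were called (100% each), and 11 unchanged genes were. Each simulated gene had a single rate and independent reads. Real sites differ within a gene and its reads are not independent, so these counts give no error rate for the real calls. Bootstrap intervals held a known difference between regions in 92.5% of 200 simulations. The simulated windows were independent of each other. Neighbouring windows of the genome had like levels, so the printed bootstrap intervals may be too narrow. Alternatives set beforehand were minimum depths of 1, 10 and 20 reads, means of per-site levels, the effective count, correction for non-conversion, a maximum depth, other region sizes, other backgrounds and each chromosome left out. Alternatives chosen after seeing the data were the gene-poorest region as centromere, the MORC6 depth without flanks, against genes of similar GC content or corrected for the ceiling, the length-matched group test, the gene profile in genes of at least 4 kb, and flanks against gene bodies within each region. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.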

Results

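DNA methylation was measured by whole-genome bisulfite sequencing in 1 library, made from 2 to 3 leaves of a single 3-week-old Arabidopsis thaliana plant of the Col-0 accession. Bisulfite turns unmethylated cytosines into bases read as T and leaves methylated cytosines as C, so the share of C among C and T reads at a cytosine is its methylation level. The library is labelled as a first-generation (T1) transformant carrying MORC6, driven by its own promoter and fused to a 9xFLAG epitope tag, in the morc6-3 mutant. MORC6 is a GHKL-type ATPase of the Microrchidia family that acts in transcriptional silencing. The series also lists RNA-seq of floral buds from 3 wild type plants, 3 morc6-3 plants and 1 transgenic line, which were not analysed here. With 1 library there was no replicate and no wild type or mutant methylome, so all comparisons are between contexts, regions and genes inside this library. The file covered 42712830 nuclear cytosines in a readable context with 828840097 C and T reads, a mean of 19.4 reads per cytosine. At least 4 reads were present at 95.5% of these cytosines and at least 10 reads at 74.1%. Exact intervals below cover counting error only, and bootstrap intervals over 100-kb windows describe the spread along the genome, not between plants.

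At the MORC6 locus, the depth of coverage was close to that of other genes. MORC6 (AT1G19100) lies on chromosome 1, with its first cytosine at 6594883 and its last at 6601350 in the coordinates of the file. The gene with its 1-kb flanks had 1.03 times the depth of the median protein-coding gene with flanks. The gene alone had a mean of 18.9 reads per cytosine against a median of 16.8 over genes, a ratio of 1.12, and 58 of the 277 genes within 500 kb had a higher depth. Against genes of similar GC content the ratio was 1.02, inside the range of 0.906 to 1.14 that holds 95% of the 1638 other genes of at least 5 kb. An added full copy on 1 chromosome would give a ratio of 1.44 under a model of the depth ceiling of the file. In that model the counted depth levels off gradually towards the ceiling. None of the 13 windows of 500 bp in the gene (0 windows) reached that ratio, and their median was 0.989. The depth therefore gave no sign of the added copy that the label of the library names. MORC6 had a CG level of 31.5% over its body (exact 95% interval 30.1 to 32.9), with 0.497% in CHG and 0.523% in CHH.

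**Figure D1:**
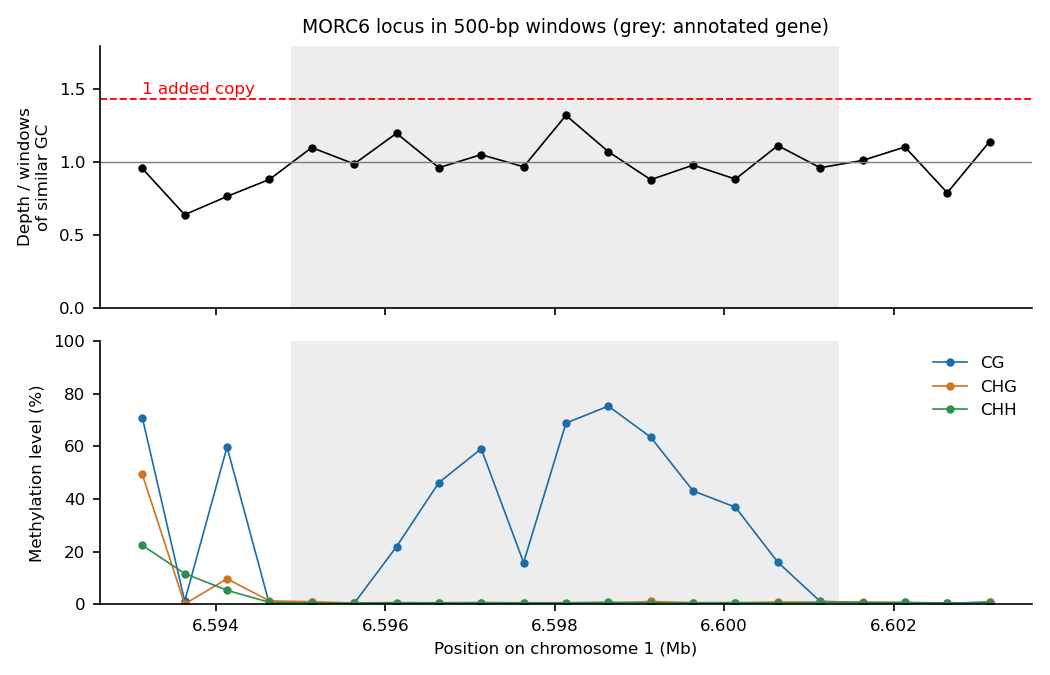
Depth relative to windows of similar GC content (upper panel, no unit) and methylation level in percent (lower panel) in 500-bp windows over MORC6 and its flanks, against position on chromosome 1 in Mb, with the gene in grey. Window depths in the gene ran from 0.881 to 1.32, all under the dashed line at 1.44, and CG methylation filled the middle of the gene.

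Non-conversion was read from the chloroplast genome, which is taken as unmethylated. Its C share was 0.568% over all contexts (exact 95% interval 0.562 to 0.574), with 0.546% in CG, 0.520% in CHG and 0.583% in CHH. In the 5 nuclear chromosomes the methylation level was 25.7% in CG (bootstrap 95% interval 24.3 to 27.0), 8.77% in CHG (8.10 to 9.48) and 2.49% in CHH (2.35 to 2.64). All 3 levels lay above the chloroplast rate of their context. Over whole chromosomes, which hold the regions near centromeres in different shares, the levels ran from 21.9% to 29.1% in CG, from 6.94% to 10.8% in CHG and from 2.23% to 2.80% in CHH.

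Single CG sites were mostly either unmethylated or fully methylated, while CHG and CHH sites seldom reached high levels. Of the 4019286 CG sites with at least 10 reads, 68.1% had a level below 10% and 21.8% a level of 80% or more. Among CHG sites 82.6% were below 10% and 2.21% at 80% or more, and among CHH sites these shares were 93% and 0.0335%. CG methylation was symmetric between the strands. Across 1413731 CG dyads with at least 10 reads on both strands, the strand levels had a Pearson r of 0.979 and a Spearman rho of 0.835. Only 385 of the 402263 CG dyads with a strand at 50% or more had the opposite strand at 10% or less (0.0957%, exact 95% interval 0.0864 to 0.106). For CAG and CTG dyads r was 0.933 and rho 0.670, and 1035 of 127123 dyads were on 1 strand only (0.814%, 0.766 to 0.865). That share was 0.268% with at least 20 reads on both strands. These correlations are across sites within 1 library, and sites are not independent replicates.

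Methylation in every context was concentrated around the centromeres. Within 2 Mb of the centromere, placed at the longest interval without cytosines, the CG level was 69.1% against 16.9% in the chromosome arms, a difference of 52.2 percentage points (bootstrap 95% interval 48.9 to 54.9). The CHG level was 33.4% against 4.11%, a difference of 29.3 points (27.5 to 31.0). The CHH level was 7.37% against 1.51%, a difference of 5.86 points (5.45 to 6.21). The difference was positive on all 5 chromosomes in each context. In CG it ran from 44.6 to 57.3 points. The exact two-sided sign-flip permutation test over the 5 chromosomes gave p = 0.063 in each context, the smallest value that 5 chromosomes allow.

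**Figure D2:**
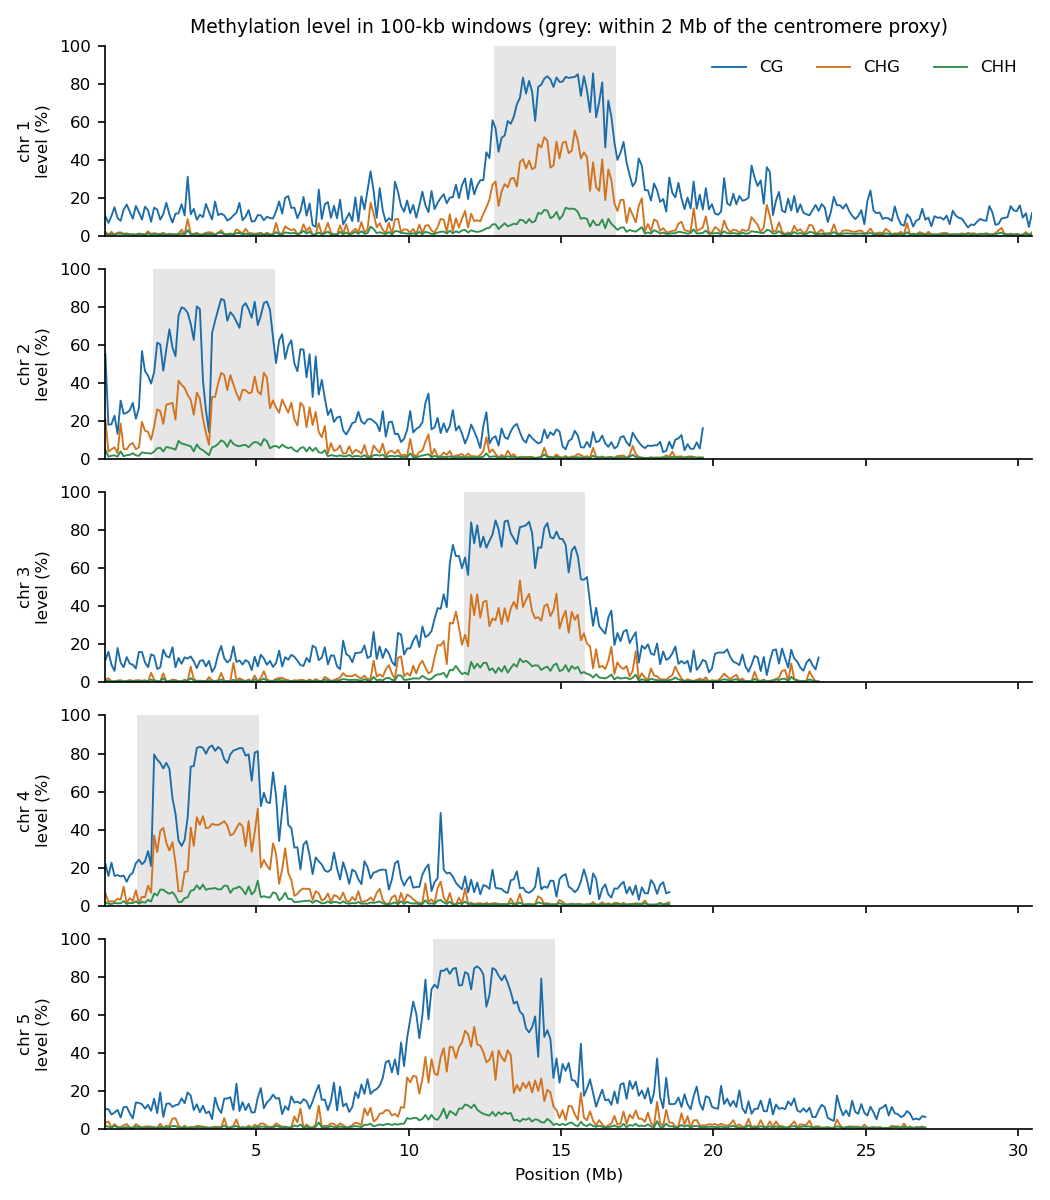
Methylation level in percent in 100-kb windows along the 5 chromosomes, against position in Mb, for CG, CHG and CHH, with the region within 2 Mb of the centromere position in grey. Levels in the grey regions averaged 69.1% in CG, 33.4% in CHG and 7.37% in CHH, against 16.9%, 4.11% and 1.51% outside them.

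Within the non-CG contexts, the bases after the cytosine set clear differences. CAA and CTA are known as sequences favoured by the chromomethylase CMT2, which maintains CHH methylation in heterochromatin, and CCG as a poor substrate of its relative CMT3. CHG methylation was lower at CCG sites, at 7.09%, than at CAG and CTG sites together, at 9.11%, a difference of -2.02 points (bootstrap 95% interval -2.34 to -1.70). The ratio of CCG to the other CHG sites was 0.627 near the centromeres (0.612 to 0.643) and 0.920 in the arms (0.891 to 0.95). CHH methylation was highest at CTA and CAA sites, with 4.67% and 4.47%, and lowest at CCT sites, with 0.893%. CAA and CTA together had 4.54% against 1.49% at the other CHH sites, a difference of 3.05 points (2.78 to 3.31). Their ratio was 4.51 near the centromeres (4.40 to 4.61) and 2.11 in the arms (2.04 to 2.17), and the log2 of the former over the latter was 1.09 (1.04 to 1.15). After subtracting the chloroplast rate, the ratios were 5.17 and 3.13 and the log2 value 0.73 (0.67 to 0.78).

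**Figure D3:**
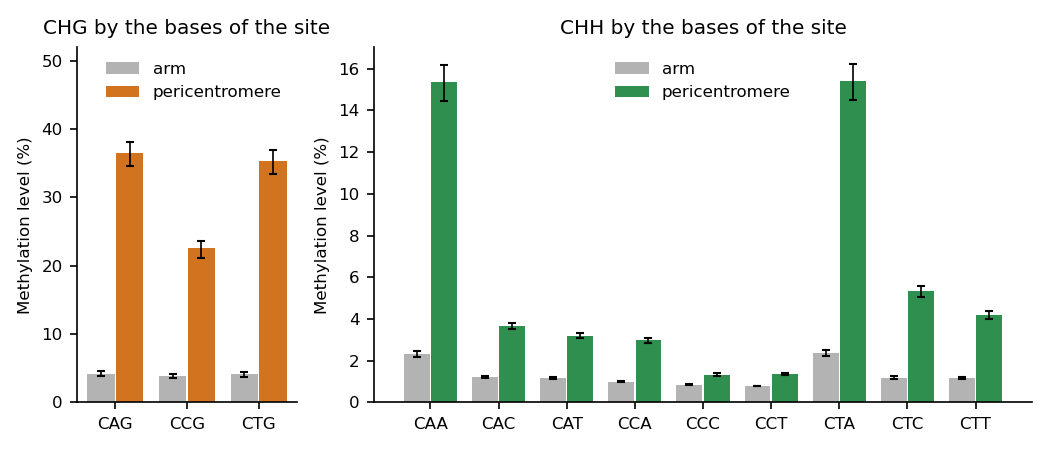
Methylation level in percent by trinucleotide, for CHG (left) and CHH (right) sites, in chromosome arms and within 2 Mb of the centromere position. Bars give summed C reads over summed C and T reads and error bars the bootstrap 95% interval over 100-kb windows. CAA and CTA reached 15.4% near the centromeres, and CCC and CCT stayed at 1.33% and 1.35%.

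Annotated pseudogenes, a class that in this gene table also takes in transposon genes, were methylated in every context, and protein-coding genes mainly in CG. Over the 3917 pseudogenes the level was 80.2% in CG, 46.7% in CHG and 10.7% in CHH. Over the 27432 protein-coding genes it was 15.6%, 1.58% and 0.811%. The differences were 64.5 points in CG (bootstrap 95% interval 63.4 to 65.4), 45.2 in CHG (44.4 to 46.0) and 9.90 in CHH (9.66 to 10.2). A separate class of 926 transcribed pseudogenes had much lower levels than the 3917, with 35.0% in CG, 14.8% in CHG and 3.41% in CHH. These were still above protein-coding genes, in CG by 19.3 points (13.3 to 26.2). Pseudogene values elsewhere in the text leave that class out. Genes of microRNAs, the precursors of small regulatory RNAs, had 34.5% in CG, 12.5% in CHG and 3.41% in CHH, above protein-coding genes by 18.9 (12.4 to 24.8), 10.9 (7.71 to 14.2) and 2.60 points (1.87 to 3.34). Genes of small nucleolar RNAs, which guide ribosomal RNA modification, were nearly free of methylation, with 1.5% in CG, 0.854% in CHG and 0.599% in CHH. For tRNA genes the difference from protein-coding genes was not detectable in any context, with a CG difference of -1.15 points (-11.9 to 11.1). Long noncoding RNA genes had less CG methylation than protein-coding genes, 13.4%, and more CHG methylation, 3.22%. Gene classes were not separated where genes overlap, so a cytosine can count in more than 1 class. The 1-kb flanks of protein-coding genes had more CHG methylation than gene bodies, 5.68% (difference 4.11 points, 3.87 to 4.34), and more CHH methylation, 1.8% (0.991 points, 0.942 to 1.04). In CG, with 15.1% in the flanks, opposite differences met. Near the centromeres flanks were higher than gene bodies, 50.6% against 35.9% (difference 14.7 points, 12.1 to 17.1), and in the arms lower, 11.98% against 14.7% (-2.67 points, -3.31 to -2.10), a split chosen after seeing the data. Over the whole genome the CG difference was not called (-0.521 points, -1.21 to 0.145), but with at least 10 reads per site a difference of -0.814 points was called. The nearest 500 bp alone were lower, with a difference of -3.93 points.

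In protein-coding genes of at least 1 kb, the CG level was 4.01% in the first 100 bp inside a gene end and rose to 39.1% in the bin centred 1950 bp inside, which only genes of about 4 kb or more reach. In the 3248 genes of at least 4 kb, a choice made after seeing the data so that every bin holds the same genes, it rose from 2.73% to 39.4%. Over all genes of at least 1 kb it was 16.6% in the bin centred 1950 bp outside the gene. CHG methylation fell across the gene end, from 6.46% in that outer bin to 1.66% in the first 100 bp inside, and CHH methylation from 2.03% to 0.849%. In pseudogenes the CG level was 77.8% just outside the end and 79.4% just inside it.

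**Figure D4:**
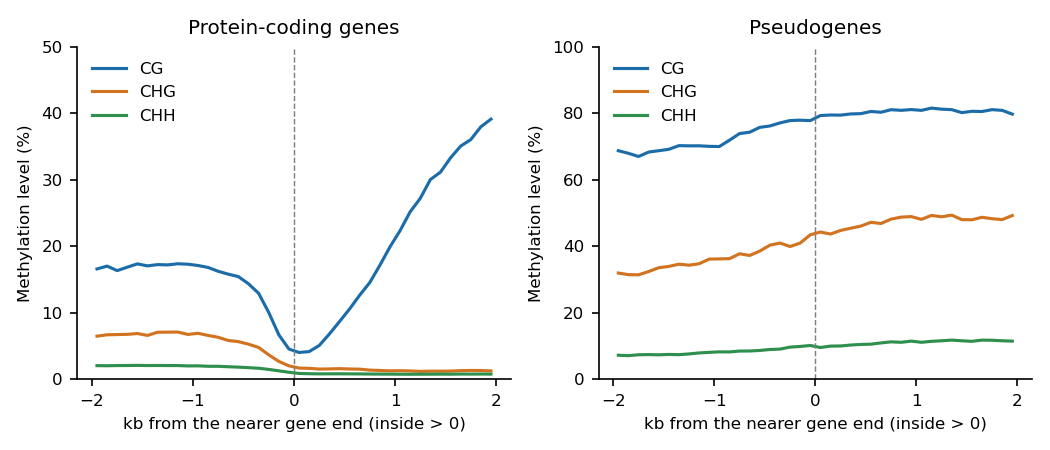
Methylation level in percent in 100-bp bins against distance in kb from the nearer gene end, negative outside the gene and positive inside, for protein-coding genes (left) and pseudogenes (right) of at least 1 kb. The CG level of protein-coding genes had its minimum of 4.01% at the gene end and reached 39.1% inside, where the innermost bins hold only genes of about 4 kb or more, and pseudogenes were methylated on both sides. The vertical scales of the panels differ.

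Gene body methylation, taken as CG methylation above the mean of protein-coding genes without CHG or CHH methylation called above theirs, was present in 5810 of the 26052 protein-coding genes tested (22.3%). A further 1850 genes (7.10%) had CHG or CHH methylation above the genic background, as transposons do, and 18392 (70.6%) had neither. Gene body methylated genes had a level of 31.8% in CG, with 0.601% in CHG and 0.557% in CHH. Their median length was 3431 bp against 1906 bp for genes with neither. Transposon-like genes had 41.0% in CG, 17.9% in CHG and 4.05% in CHH, and 522 of them (28.2%) lay within 2 Mb of a centromere position. The test was a one-sided exact binomial test of each gene's reads against the mean of all protein-coding genes, with Benjamini-Hochberg adjustment at 0.05. Against the chloroplast rate in place of the genic mean, 13832 genes had CG methylation alone, of which 5420 were shared with the 5810.

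Several transcription factor and enzyme families held few gene body methylated genes. Among MYB factors, regulators of metabolism and development, 1 of 114 was gene body methylated (0.877%), against 22.4% of the other genes (Fisher's exact test, adjusted p = 2.9e-10). Among cytochrome P450 genes, which encode oxidising enzymes, the count was 15 of 219 (6.85%, Fisher's exact test, adjusted p = 7.5e-09). It was 4 of 67 in the WRKY factors, regulators of defence (5.97%, Fisher's exact test, adjusted p = 0.0015). None of the 38 nuclear photosynthesis genes was gene body methylated (0 genes, which allows a share of up to 9.25% by the exact interval, adjusted p = 0.00043), nor any of the 32 expansins (adjusted p = 0.0013) or 19 histone genes (adjusted p = 0.027). The DNA methylation pathway was higher, with 16 of 29 genes (55.2%, Fisher's exact test, adjusted p = 0.00043). These are two-sided Fisher's exact tests over 18 groups with Benjamini-Hochberg adjustment. Adjusted over the list alone, the counts of gene body methylated genes were the same in each of these groups except the cytochrome P450 genes, with 14. Since longer genes are more often gene body methylated, the groups were also set against random genes of the same lengths. These lengths were matched after the data had been seen. MYB, P450 and WRKY genes stayed lower in that permutation test (adjusted p = 0.0012, 0.0012 and 0.031). In the same permutation test the calls ended for expansins (adjusted p = 0.30), photosynthesis genes (0.30), histone genes (0.94) and the DNA methylation pathway (0.94), for which 59.6% was expected at the same lengths.

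Genes known as targets of RNA-directed DNA methylation or as imprinted genes differed widely from each other in methylation, over and beside the gene. Of the 17 listed genes measured, 10 had a CG level above 10% in the 1-kb flanks, 4 had a CHG level above 10% and 0 a CHH level above 10%. In the body these counts were 10, 3 and 0. HDG9, an imprinted homeobox gene, had flank levels of 81.9% in CG (exact 95% interval 79.7 to 83.8), 25.5% in CHG (23.0 to 28.1) and 5.75% in CHH (5.37 to 6.16). QQS, an orphan gene known for variable silencing, had 68.3%, 21.0% and 6.50% in its flanks and 17.4% in CHG over its body. ALN, which encodes allantoinase, had 61.8%, 18.5% and 2.97%. SDC, an F-box gene silenced by non-CG methylation of its promoter repeats, had 49.1%, 26.5% and 4.35%. The lowest flank CG levels of the list were 0.555% at RMG1 and 0.557% at EPF2. Of the 17 genes, 2 were gene body methylated and 7 transposon-like.

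Of the 29 genes of the DNA methylation pathway, 22 had a CG level above 10% over the body, and none had a CHG or CHH level above 10% there (0 genes each). DCL3, the Dicer that makes the small RNAs of the pathway, had the highest body CG level, 55.1% (53.7 to 56.5). It was followed by NRPD1, the largest subunit of RNA polymerase IV, with 53.0% (51.9 to 54.1), the silencing factor MOM1 with 50.1% (48.9 to 51.4) and the RNA-dependent RNA polymerase RDR2 with 49.6% (47.9 to 51.4). The lowest were DRM1, with 0.574%, and DML3, with 0.891%. In the flanks 12 of the 29 genes had a CG level above 10%. DMS3 was the single gene with a CHG level above 10% there, 22.9% (21.1 to 24.7). In the MORC family, MORC1 had a body CG level of 21.8% and MORC2 of 3.33%, and no member had a body CHG or CHH level that passed the test against the chloroplast rate.

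The 10 developmental genes, listed because they are known as unmethylated, were close to the chloroplast rate over their bodies, with 0 genes above 10% in any context and CG levels from 0.318% at CLV3 to 1.12% at STM. Their flanks stayed below 10% as well, and the highest flank CG level was 8.11% at FLC, the flowering repressor. The 10 leaf photosynthesis genes also had 0 bodies above 10% in any context, while 3 had flank CG levels above 10%. These were RBCS1B, a small subunit gene of Rubisco, with 42.2% (39.9 to 44.4), the photosystem I gene PSAD1 with 34.5% (32.6 to 36.5) and the antenna protein gene CAB1 with 16.3% (14.2 to 18.5). RBCS1B and PSAD1 also had flank CHG levels of 15.3% and 20.1%. Of the 9 constitutively expressed genes, 2 had body CG levels above 10%, RPB2 with 37.6% and PP2AA3 with 30.4%. Over the 6 lists with measured genes, 195 of 468 values lay above the chloroplast rate (one-sided exact binomial test, Benjamini-Hochberg adjustment over the 468 tests).

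The protein-coding genes with the highest CHG levels were methylated like transposons in all contexts. AT2G22440 on chromosome 2 had 77.6% in CHG (exact 95% interval 74.5 to 80.6), 92.6% in CG and 17.3% in CHH. AT1G31095 followed with 76.7% in CHG (74.2 to 79.0) and AT5G18636 with 75.7% (73.3 to 77.9), and the tenth gene, AT5G15685, had 71.1%. The highest CG level among gene body methylated genes was 72.2% at AT2G23945 (69.5 to 74.8), with 1.74% in CHG. AT2G11225 had 71.5%, the rhomboid-like gene RBL5 65.3% and ACC1, the acetyl-CoA carboxylase gene, 64.2% (63.1 to 65.3). The immune receptor gene TAO1 had 62.7% and EOL1 61.9%.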

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

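Of the tests below, those of conversion and of the ratio between contexts were chosen after the levels had been seen. The mitochondrial genome, whose own cytosines enter none of the comparisons between nuclear regions or genes, had C shares far above the chloroplast rate. Its level was 17.8% in CG, 9.75% in CHG and 2.58% in CHH, against 0.546%, 0.520% and 0.583% in the chloroplast.

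Incomplete conversion of mitochondrial DNA would raise the contexts alike, and the CG level was 6.93 times the CHH level, which argues against it. Chromosome 2 carries a large insertion of mitochondrial DNA, and 263 kb of it share 100-base sequences with the mitochondrial genome. The 2 copies had like levels there, 22.3% in CG at the chromosome 2 cytosines and 20.9% at the mitochondrial ones, so reads may have been split between them. These chromosome 2 cytosines were kept in the nuclear levels and comparisons. The CG difference between pericentromere and arm was smallest on chromosome 2, 44.6 points, and the effect of such reads on it was not tested. Mitochondrial cytosines with no nuclear match within 100 bp still had 12.98% in CG, above the 10% set beforehand as the bound against nuclear copies, so the copies in the assembled chromosomes do not account for the whole signal. Copies missing from the assembly stay open, since the insertion is known to be longer in plants than assembled, and the ratio of CHG to CG, chloroplast rates subtracted, at unmatched cytosines (0.524) lay close to that at matched ones (0.540). Methylation of mitochondrial DNA itself was not tested, and the design gives no biological explanation to test.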

How the results depend on the processing

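No paired analysis was possible because the wild type and morc6-3 libraries were not analysed here, and their plant numbers 1 to 3 belong to different plants, with nothing in the labels that ties them. Exons and upstream sides were not run, for lack of exons and strands. Every region difference in CG, CHG and CHH kept its direction and its call (in CG the size was 49.6 points with 1 Mb and 38.9 with 4 Mb) with regions of 1 and 4 Mb, at least 10 reads, per-site means and the gene-poorest centromere positions, the last chosen after seeing the data, as did both sub-context comparisons with 10 reads and per-site means. Genome levels moved beyond counting error under each setting. In CG, CHG and CHH they were 25.7%, 8.79% and 2.5% with at least 1 read, 25.6%, 8.70% and 2.47% with at least 10 reads, 26.3%, 9.10% and 2.61% as means of per-site levels, 25.7%, 8.78% and 2.5% with the effective count, 25.7%, 8.79% and 2.5% without sites above 63 reads, and 25.3%, 8.29% and 1.92% corrected for non-conversion. Leaving out each chromosome gave 25.0% to 26.9% in CG, 8.36% to 9.39% in CHG and 2.43% to 2.59% in CHH. The mitochondrion in place of the chloroplast gave a C share of 6.33%, which the difference between its contexts argues against reading as a non-conversion rate. Dyads on 1 strand only made up 0.131% in CG and 0.268% in CAG and CTG with at least 20 reads. The CG difference between flanks and gene bodies was called at -0.814 points with at least 10 reads and at -3.93 with 500-bp flanks. Split by region after seeing the data, it was 14.7 near the centromeres, the opposite direction, and -2.67 in the arms. For tRNA genes the CG difference, not called in any setting, changed sign to 0.731 with per-site means. With the chloroplast rate as background 13832 genes were gene body methylated in place of 5810, and 2762 transposon-like in place of 1850. The MORC6 depth ratio was 1.04 against genes within 500 kb and 1.14 by median depth. With choices made after seeing the data it was 1.12 without flanks and 1.14 corrected for the ceiling. Length matching, also chosen after seeing the data, gave 6 called groups in place of 8, with 4 in both. Both new ones are lists chosen for their known methylation and are not counted as findings. Expansins, photosynthesis genes and histone genes could not have been called lower there, since even their count of 0 genes is not called. The CG rise inside genes was 36.7 points in genes of at least 4 kb, chosen after seeing the data, in place of 35.1. Among all values under an alternative, 40 of the main results and 58 of the others kept their direction and call, stayed within counting error or, for counts, changed less than 1.5-fold, as the length-matched groups and the transposon-like genes did, and 41 main results and 1 other moved, 3 became called, 1 main result and 1 other reversed and 1 was weaker. Where no cause is named above, the cause was not tested. At this depth, levels below about the chloroplast rate of 0.568% cannot be told from incomplete conversion.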

Other observations

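Pseudogenes in the chromosome arms were not simply less methylated than those near the centromeres. Their CG level was lower, 73.7% against 82.9%, a difference of 9.27 points (bootstrap 95% interval 7.11 to 11.7). Their CHH level was higher, 11.5% against 10.4% (difference near centromere minus arm -1.09 points, -1.62 to -0.565), and for CHG, 46.9% and 46.7%, the interval of the difference held 0 (-1.92 to 1.57). The 281 arm pseudogenes of at least 4 kb had 51.3% in CHG and 13.1% in CHH, and the 367 under 1 kb had 34.6% and 7.77%. Near the centromeres the 503 long ones had 47.7% and 10.8%, and the 684 short ones 39.3% and 8.51%.

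Beside MORC6, the window from 6592883 to 6593382 had levels of 71.0% in CG, 49.3% in CHG and 22.4% in CHH, a window named after its values were seen. The next window, to 6593882, had 11.6% in CHH with 1.14% in CG and 0% in CHG. It held 112 cytosines over all contexts, and no intervals were computed for single windows. The window from 6593883 to 6594382 had 59.8% in CG, 9.63% in CHG and 5.24% in CHH. From 6594383 to the start of the gene the CHH level was 0.660%, close to the chloroplast rate.

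All tests in this paragraph were chosen after the depth had been seen. The MORC6 locus showed no excess depth although the label names an added copy driven by the MORC6 promoter. GC bias hiding a copy is argued against by the ratio of 1.02 against genes of similar GC content. A depth ceiling hiding it is argued against by the ratio of 1.14, corrected under the same model of the ceiling. The 1.44 of an added copy holds with the ceiling in place, and the expected ratio without a ceiling is higher still. A plant without an added copy would give a ratio inside the range of other genes, as the value of 1.02 is, so a plant that lost or never carried the construct may be a candidate explanation. A construct with a short contiguous part of the locus stays open, since the highest 500-bp window had a ratio of 1.32 and single gene windows of similar GC content spread from 0.723 to 1.32 without any copy added. A construct of spliced sequence stays open too, since exon positions were not available and the windows could not follow them. A promoter copy would lie beside the gene, where the 8 flank windows had ratios from 0.641 to 1.14. The windows next to the gene had 0.883 and 1.01, below the 1.04 to which window spread could lower the ratio of an added copy. Since the promoter's length in the construct and the strand of the gene were not available, these windows do not settle it.

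The excess of CAA and CTA methylation over other CHH sites was larger near the centromeres than in the arms, with a log2 ratio of 1.09, and these tests were set before their results were seen. Dilution by non-conversion in the weakly methylated arms as the whole cause is argued against by the value of 0.73 (0.67 to 0.78) after subtracting the chloroplast rate. More pseudogene sequence near the centromeres as the whole cause is argued against by the value within pseudogenes, 0.18 (0.15 to 0.22), though most of the difference was gone there. In the arms the excess was 5.25 in pseudogenes of at least 4 kb and 4.87 in those under 1 kb, a log2 difference of 0.11 (0.02 to 0.20). Longer pseudogenes thus had the larger excess, by a small margin given that bootstrap intervals may be too narrow. By number, however, long pseudogenes were no larger a share near the centromeres (503 of 2735) than in the arms (281 of 1182). The cause of the difference between regions stays open.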
